A study of Mus musculus with 3 samples.

How the data were processed

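Mesangial cells are the contractile pericyte-like cells that hold the capillary loops of the kidney glomerulus together. Per the labels' protocols, they were taken from the kidney cortex of adult male CD-1 mice that carry a bacterial artificial chromosome driving green fluorescent protein from Meis1 regulatory sequence. Glomeruli were caught on a sieve after collagenase digestion, taken apart with trypsin and sorted by fluorescence. Each of the 3 samples came from 1 kidney and none was pooled. The labels do not say whether the 3 kidneys came from separate mice, so the spread given here is the spread between these samples, part of which may be technical. There was 1 group and no control population, so no comparison between conditions was made.

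RNA was amplified once with the WT-Ovation Pico system, labelled with biotin and hybridised to an Affymetrix mouse gene array, 1 array per sample, per the labels' protocols. The deposited values are log2 values of probe set signal made with Affymetrix Expression Console, per the submitters' processing notes. The software version, the background correction and the summary method are not given in the sources used here. The log base was inferred from the values, since the highest value of 14.39 lies within the range of a 16-bit scanner only in base 2. The sorted values of the 3 arrays nearly coincided, as after a quantile-type normalization, and the array medians were 7.53, 7.56 and 7.54. Scale and centring beyond this are unknown. The values were used as deposited.

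Many probe sets carried identical values on different arrays. Of the 35557 probe sets, 14310 (40.2%) had 1 value on all 3 arrays, 8166 had the same value on exactly 2 arrays, and 13081 had 3 different values. If such values come from the processing, standard deviations over the 3 samples are too small for many genes, and an SD of 0 does not mean that a gene was measured without error. The number of arrays limits the precision of every value.

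Genes were named from the platform annotation supplied with the values. It listed 23410 of the probe sets, of which 21789 had exactly 1 gene symbol and 1621 had several, and 12147 were not listed and stay unnamed here. Symbols were updated through the Entrez gene number with the RefSeq gene table of the mouse assembly GRCm38.p6, which matched 21698 probe sets, and 91 kept the symbol of the annotation. Of several probe sets of a gene, the one with the highest mean was used, which concerned 983 genes. Probe sets with several symbols named no gene.

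A gene was called above the threshold when its value passed, on all 3 arrays, the 95th percentile of that array's probe sets for gene families that kidney cells should not express. These were 1268 probe sets for olfactory, vomeronasal and trace amine receptors and keratin-associated proteins, and the silent-gene thresholds were 7.48, 7.46 and 7.40 on arrays 1, 2 and 3. The remaining 18686 named genes formed the background. Probe sets differ in affinity, so a value was set against the threshold and against the same gene in other samples, and no order of amount between genes is implied.

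The 30 gene lists held 472 genes, of which 437 were measured and 35 had no probe set of their own in the annotation and are not analysed here. They covered mesangial markers, contractile smooth muscle, renin cells, podocytes, endothelium, parietal epithelium, proximal tubule, the later tubule segments, fibroblasts, macrophages, lymphocytes and erythroid cells. Neurons, hepatocytes, striated muscle and spermatids stood for cells outside the kidney. Extracellular matrix, integrins, vasoactive receptors with cGMP signalling, ion channels, growth factor signalling, stromal transcription factors, TALE homeobox genes, Hox genes of groups 1 to 11 and of groups 12 and 13, cytokines, immediate early and stress genes, proliferation, housekeeping and a sex check completed them. The share of each of 29 lists above the threshold was compared with all other named genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 29 lists, called at an adjusted p of 0.05, with the sex check left untested. This is a test over genes, which are not replicates of the cells. A placing of each list median among 10000 random lists of the same size is not reported, because it would set probe sets of different affinity against each other. The median deviation of a list's members on each array was placed among 10000 random lists matched on level in 20 bins, and called outside below the 2.5th or above the 97.5th percentile.

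The lists, the threshold, the tests, the alternatives and the rule for named genes were fixed before the data were examined, apart from those said below to be chosen later. The rule names all mesangial, TALE and sex check genes, the 3 members with the highest and the 1 with the lowest mean of every other list, the 20 genes with the highest means, and the 10 genes above the threshold with the largest SD. Other genes are said to be chosen after their values were seen. The alternatives chosen then were the 90th and 99th percentile, olfactory receptors alone as reference, the mean of the arrays or at least 2 of the 3 arrays above the threshold, the mean of several probe sets, quantile normalization with limma, median-centring, leaving out each sample, leaving out genes that stand in several lists, genes above the threshold alone, and the silent genes added to the background. A threshold raised by 1 on the log2 scale, the mean of the deviations in place of their median, and correlations over genes without ties were added after the data were seen.

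The share test and the list shift were tested on simulated data built on the 18686 genes. The share test called 5 of 5 lists of 20 genes with 19 above the threshold, 5 of 5 lists with 3 above it, and 0 of 15 random lists. The list shift placed outside 5 of 5 lists raised by 0.3 on 1 array and 1 of 45 random shifts. The simulated values had an SD of 0.15 and no ties, whereas 51.1% of the named genes were identical on all 3 arrays. The raise of 0.3 also exceeded the largest observed median shift of 0.08. The simulation therefore checks the scripts and does not show how the list shift behaves on tied values or small shifts. Calculations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, figures used matplotlib 3.10.9, and quantile normalization used limma 3.58.1 in R 4.3.3.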

Results

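The transcripts of mesangial cells sorted from adult mouse glomeruli were profiled on 3 arrays, 1 for each kidney. The aim was to describe which genes lay above background in the sorted cells. Without a control population, RNA carried over from other kidney cells cannot be told apart from expression in mesangial cells. All values are deposited log2 signals, given as the mean ± SD over n = 3 samples, and samples are called 1, 2 and 3. The arrays ranged from 3.36 to 14.39, from 3.31 to 14.39 and from 3.41 to 14.33. The median of the silent reference probe sets was 5.56 on each array.

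In the sorted cells 10833 of 18686 named genes (58.0%) lay above the silent-gene threshold on all 3 arrays. The threshold was permissive. Of the 1252 silent reference genes 59 (4.71%) passed it, and the same share of the named genes would be 881. Of 39 measured genes of neurons, hepatocytes, striated muscle and spermatids 6 passed (15.4%). With the threshold raised by 1, an alternative chosen after the data were seen, 6118 named genes (32.7%), 12 silent genes (0.958%) and 1 of the 39, the troponin gene Tnnt2, remained above. The number of genes depended on this choice, and a gene less than 1 above the threshold was close to background.

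Most mesangial markers lay more than 1 above the threshold. Of the 16 measured, 15 lay above the threshold on all 3 arrays, with means from 9.41 to 13.10, against 57.9% of other genes (adjusted p = 0.0160, Fisher's exact test). All 15 also passed the threshold raised by 1 (adjusted p = 1.69e-05, Fisher's exact test). The integrin subunit gene Itga8, whose product anchors mesangial cells to the matrix, had 12.96 ± 0.01, the platelet-derived growth factor receptor gene Pdgfrb 12.03 ± 0.06 and the transcription factor gene Gata3 12.24 ± 0.06. The heparin-binding growth factor gene Ptn had 13.10 ± 0.12, Igfbp5, for an insulin-like growth factor binding protein, 12.71 ± 0.20, and the angiotensin II receptor gene Agtr1a 12.48 ± 0.05. The soluble guanylate cyclase subunits Gucy1a1 and Gucy1b1 had 11.81 ± 0.02 and 10.58 (identical on the 3 arrays). Art3 had 11.63 ± 0.16, the ectonucleotidase gene Nt5e 11.48 ± 0.02, the transcription factor gene Ebf1 11.25 ± 0.02, Fhl2 11.13 ± 0.05 and the protein kinase C gene Prkca 10.99 ± 0.04. The intermediate filament gene Des had 10.55 ± 0.11 and the proteoglycan gene Cspg4 9.41 ± 0.04. Tbx18, a transcription factor of the renal stroma, was the 1 measured member not above the threshold, at 6.12 on all 3 arrays. The share did not pass the test at the 90th percentile threshold (adjusted p = 0.0773, Fisher's exact test) or when the 8 markers that stand in other lists were left out (8 of 8 above, adjusted p = 0.0540, Fisher's exact test). Serpine2 and Ednra were not analysed here.

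Meis1, whose regulatory sequence drove the fluorescent protein used for the sort, had 9.39 ± 0.05 and lay above the threshold in all 3 samples (9.33, 9.42 and 9.42). Of the 10 measured TALE homeobox genes, some of which encode partners of Hox proteins, 9 lay above the threshold. This share did not pass the test (adjusted p = 0.0902, Fisher's exact test) unless the silent genes joined the background (adjusted p = 0.0457, Fisher's exact test). Meis2 had 10.55 ± 0.07, Tgif2 9.44 ± 0.03 and Pbx2 9.22 (identical on the 3 arrays), and with Meis1 these were the 4 that also passed the threshold raised by 1. Meis3 had 8.37, Pbx3 8.32 ± 0.05, Pknox1 8.20 ± 0.15, Pbx4 8.19 ± 0.06 and Tgif1 7.99 ± 0.11. Pknox2, at 6.71, was not above the threshold.

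Hox genes, the positional regulators of the body axis, split by paralog group. Of the 31 measured genes of groups 1 to 11, 27 lay above the threshold (adjusted p = 0.00742, Fisher's exact test), and of the 6 of groups 12 and 13 none did (adjusted p = 0.0160, Fisher's exact test). A direct comparison of these shares, chosen after the data were seen, gave p = 9.03e-05 (two-sided Fisher's exact test). All 4 clusters took part, with 8 of 10 Hoxa, 7 of 9 Hoxb, 6 of 9 Hoxc and 6 of 9 Hoxd genes above the threshold. Hoxc6 had 9.82 ± 0.04, Hoxc9 9.72 ± 0.06 and Hoxb5 9.69 ± 0.01. Hoxc11, at 5.51 on each array, was 1 of the 4 genes of groups 1 to 11 that were not above the threshold, and the others, chosen after their values were seen, were Hoxa2, Hoxb9 and Hoxd1. In groups 12 and 13, Hoxd13 had 7.05, Hoxa13 6.81, Hoxc13 6.78 and Hoxd12 6.48, each identical on the 3 arrays. With the threshold raised by 1, 17 of the 31 remained above (adjusted p = 0.0348, Fisher's exact test), and 0 of 6 no longer passed the test (adjusted p = 0.258, Fisher's exact test).

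**Figure D1:**
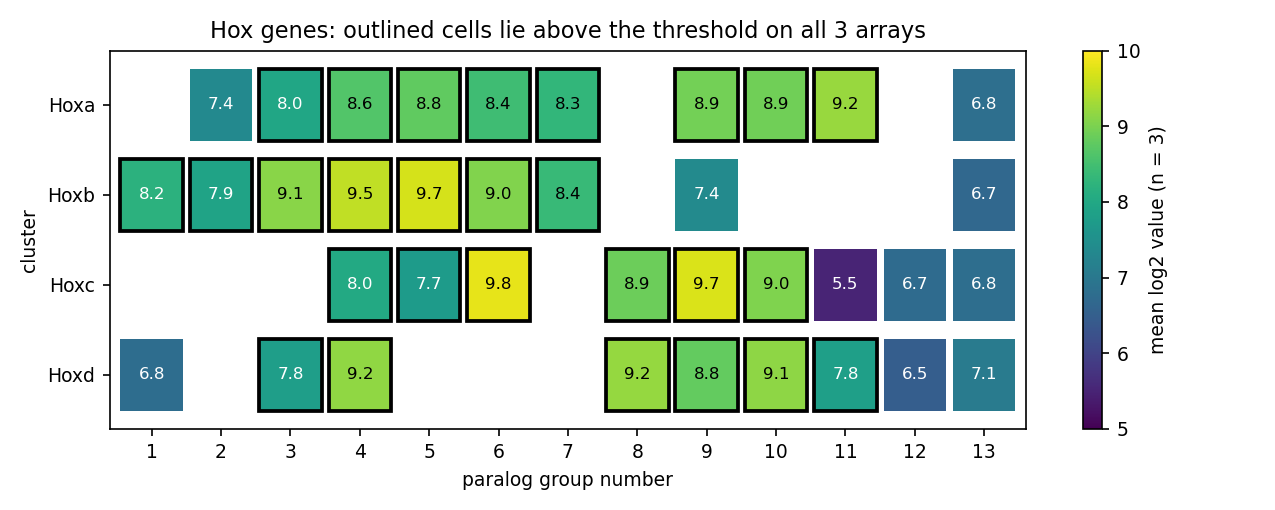
Mean log2 value over the 3 samples of each measured Hox gene, by cluster (vertical axis) and paralog group (horizontal axis), with colour and printed number giving the mean. Outlined cells are the 27 genes above the silent-gene threshold on all 3 arrays, none of which lies in groups 12 and 13, and blank positions had no measured gene.

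Most contractile smooth muscle and vasoactive genes lay above the threshold. Of 17 contractile smooth muscle genes 14 lay above the threshold, among them the actin-binding gene Cald1 at 12.87 ± 0.01, the myosin light chain gene Myl9 at 12.53 ± 0.28 and the G protein regulator Rgs5 at 11.68 ± 0.06, while Synpo2 at 7.09 ± 0.03 did not. The share missed the test (adjusted p = 0.0902, Fisher's exact test) but passed it without sample 1 (15 of 17, adjusted p = 0.0321, Fisher's exact test) and at the threshold raised by 1 (13 of 17, adjusted p = 0.00161, Fisher's exact test). Of 19 vasoactive receptor and cGMP genes 16 lay above the threshold (adjusted p = 0.0419, Fisher's exact test), among them Agtr1a and Gucy1a1 as above and the cGMP-dependent kinase gene Prkg1 at 11.02 ± 0.07. The prostaglandin receptor gene Ptger3, at 6.41, was not. With 16 of 19 still above, this call was lost without sample 1 (adjusted p = 0.0641, Fisher's exact test), where the share of other genes rose to 58.9%. It was lost with the same 16 of 19 at the 90th percentile threshold (adjusted p = 0.386, Fisher's exact test) and with olfactory receptors alone (adjusted p = 0.0825, Fisher's exact test), among other alternatives. The call held at the threshold raised by 1 (15 of 19, adjusted p = 0.000344, Fisher's exact test). Of 15 ion channel genes 9 lay above the threshold (adjusted p = 1, Fisher's exact test), with the calcium-activated chloride channel gene Ano1 at 11.55 ± 0.07 and the cation channel genes Trpc1 at 11.42 ± 0.09 and Trpc4 at 10.23 ± 0.07. The large-conductance potassium channel gene Kcnma1 had 6.49 and was not above it. All 3 measured genes of the renin cell list lay above the threshold (adjusted p = 0.372, Fisher's exact test). They were the connexin genes Gja5 at 12.88 ± 0.07 and Gja4 at 8.55, and Crip1 at 10.42 ± 0.32, whereas Ren1 and Akr1b7 were not analysed here.

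Most matrix, integrin and growth factor genes lay above the threshold, a share that passed the test for the matrix and growth factor lists and not for the integrins. Of 28 extracellular matrix genes 24 lay above the threshold (adjusted p = 0.0160, Fisher's exact test), with the secreted matrix protein gene Sparc at 13.19 (identical on the 3 arrays), the small proteoglycan gene Bgn at 12.16 ± 0.08 and the calcification inhibitor gene Mgp at 11.37 ± 0.25. The large proteoglycan gene Vcan, at 6.10, was not above it. At the threshold raised by 1, 14 of the 28 remained and the share did not pass (adjusted p = 0.116, Fisher's exact test). Of 13 integrin genes 10 lay above the threshold (adjusted p = 0.372, Fisher's exact test), with Itgb1 at 12.42 ± 0.04, Itga4 at 11.85 ± 0.04 and Itga1 at 11.27 ± 0.03, and Itgb8 at 6.51 ± 0.03 not above it. Of 28 genes of PDGF, TGF-beta and IGF signalling 23 lay above the threshold (adjusted p = 0.0301, Fisher's exact test), and 21 passed the threshold raised by 1 (adjusted p = 8.12e-05, Fisher's exact test). Igfbp7 had 13.19 ± 0.03 beside Igfbp5 and Pdgfrb given above, and Igfbp6, at 7.35, was not above it. Without genes that stand in several lists this share was 80.0% (adjusted p = 0.0540, Fisher's exact test). Of 23 stromal transcription factor genes 16 lay above the threshold (adjusted p = 0.391, Fisher's exact test), with the nuclear receptor gene Nr2f2 at 11.53 and the zinc finger gene Zeb2 at 11.34 beside Gata3. Foxd1, a marker of the embryonic renal stroma, had 6.05 and was not above it.

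Markers of the other glomerular cells divided within each list. Of 21 endothelial genes 18 lay above the threshold (adjusted p = 0.0312, Fisher's exact test), with Cd34 at 11.99 ± 0.00, the endoglin gene Eng at 11.17 ± 0.17 and the angiopoietin receptor gene Tek at 10.78 ± 0.12, and with Sox17 at 6.58 not above it. The endothelial genes Kdr at 7.57, Pecam1 at 7.61 ± 0.05 and Cdh5 at 7.66 ± 0.05, chosen after their values were seen, lay less than 1 above the threshold. Emcn at 10.38 ± 0.19, Ehd3 at 10.42 ± 0.24, Plvap at 9.35 ± 0.03 and Ptprb at 9.28 ± 0.04, chosen likewise, lay more than 1 above it. At the threshold raised by 1 the share was 11 of 21 (adjusted p = 0.116, Fisher's exact test). Of 20 podocyte genes 16 lay above the threshold (adjusted p = 0.108, Fisher's exact test), and 6 passed the threshold raised by 1, a share below that of other genes (30% against 32.7%, adjusted p = 1, Fisher's exact test). The list was called without genes that stand in several lists (84.2%, adjusted p = 0.0489, Fisher's exact test). The adaptor gene Cd2ap had 11.21, Plekhh2 10.51 ± 0.10 and the transcription factor gene Wt1 10.15 ± 0.08, while the phosphatase gene Ptpro at 6.75 ± 0.08 was not above it. The slit diaphragm gene Nphs1, at 7.39 ± 0.06, was not above it either, while Podxl at 7.63 and Synpo at 8.26 ± 0.16 were above it by less than 1, all 3 chosen after their values were seen. Of 6 parietal epithelial genes 3 lay above the threshold (adjusted p = 0.847, Fisher's exact test), which were Cd24a at 12.01 ± 0.33, Cd9 at 7.56 ± 0.09 and Pax8 at 7.56, with Cldn1 at 7.35 ± 0.58 not above it.

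No tubule gene lay more than 1 above the threshold on all 3 arrays, although the uromodulin gene Umod did in samples 1 and 2, Calb1 in samples 2 and 3 and the proximal tubule gene Kap, chosen after its values were seen, in sample 2 (8.44, 8.51 and 7.17 in samples 1, 2 and 3). Of 18 proximal tubule genes 6 passed the threshold (adjusted p = 0.0902, Fisher's exact test) and none the threshold raised by 1 (adjusted p = 0.00540, Fisher's exact test). The transporter genes Slc22a12 and Slc34a1 had 8.36 and 8.15 ± 0.16, the transcription factor gene Hnf4a 8.04, and Fbp1, at 6.06, was not above the threshold. Of 18 genes of the loop, distal and collecting tubule 11 passed (adjusted p = 1, Fisher's exact test) and none at the threshold raised by 1 (adjusted p = 0.00540, Fisher's exact test). Umod had 9.51, 9.18 and 8.22 in samples 1, 2 and 3, and Calb1 7.72, 8.66 and 8.49. The means were 8.97 ± 0.67 and 8.29 ± 0.50. The water channel gene Aqp2 had 8.09 ± 0.00, and Atp6v0d2, at 5.54 ± 0.15, was not above the threshold.

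Most leukocyte genes were not above the threshold. Of 20 macrophage genes 5 passed (adjusted p = 0.0160, Fisher's exact test) and none at the threshold raised by 1 (adjusted p = 0.00236, Fisher's exact test), with the chemokine receptor gene Cx3cr1 at 8.03 ± 0.00, Cd68 at 7.85 ± 0.07, Aif1 at 7.75 and Adgre1 at 5.56, which was not above it. Without sample 1, 7 of the 20 passed and the call was lost (adjusted p = 0.0709, Fisher's exact test). Of 9 lymphocyte genes Cd3e alone passed, at 7.78 (adjusted p = 0.0160, Fisher's exact test), while Cd8a had 7.41 ± 0.05, Cd79b 7.20 ± 0.05 and Cd79a 5.19 ± 0.01. At the 90th percentile threshold both calls were lost, with 55% of macrophage genes (adjusted p = 0.386, Fisher's exact test) and 33.3% of lymphocyte genes above (adjusted p = 0.0773, Fisher's exact test). Of 11 fibroblast genes 7 passed (adjusted p = 0.875, Fisher's exact test), with Pdgfra at 11.16 ± 0.13, Gsn at 9.36 ± 0.05, the collagen gene Col1a2 at 8.80 and Lum, at 5.33, not above it. Of 4 erythroid genes Bpgm at 8.63 and Alas2 at 7.69 passed (adjusted p = 1, Fisher's exact test), and Epb42 at 7.08 and Car1 at 6.20 ± 0.11 did not. The globin genes were not analysed here.

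Cells from outside the kidney served as a check of the threshold. None of 10 neuronal genes passed it (adjusted p = 0.00497, Fisher's exact test), with Syt1 at 7.26, Syn1 at 7.21, Slc17a7 at 7.10 ± 0.01 and Nefm at 5.82 ± 0.02. Of 9 hepatocyte genes Apoa2 alone passed, at 7.97 (adjusted p = 0.0160, Fisher's exact test), and Hpx had 7.36 ± 0.02, Apob 6.72 and Cyp3a11 4.33 ± 0.05. Of 10 spermatid genes Prm2 alone passed, at 7.89 (adjusted p = 0.0160, Fisher's exact test), and Tnp2 had 7.47 ± 0.05, Prm1 7.45 and Akap4 5.03. With olfactory receptors alone as reference the spermatid call was lost (adjusted p = 0.163, Fisher's exact test). Of 10 striated muscle genes 4 passed (adjusted p = 0.427, Fisher's exact test), with Tnnt2 at 9.54 ± 0.44, Ckm at 8.08, Acta1 at 7.93 and Myl2, at 6.48, not above it. At the threshold raised by 1, where fewer of the other genes pass as well, no neuronal, hepatocyte, spermatid or lymphocyte gene remained and none of these 4 shares passed the test (each adjusted p = 0.0708, Fisher's exact test). The Y-linked genes Eif2s3y at 9.82 ± 0.18, Kdm5d at 9.43 ± 0.16 and Uty at 8.84 ± 0.08 were above the threshold and Xist at 5.72 ± 0.01 was not, in samples whose labels give male mice.

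**Figure D2:**
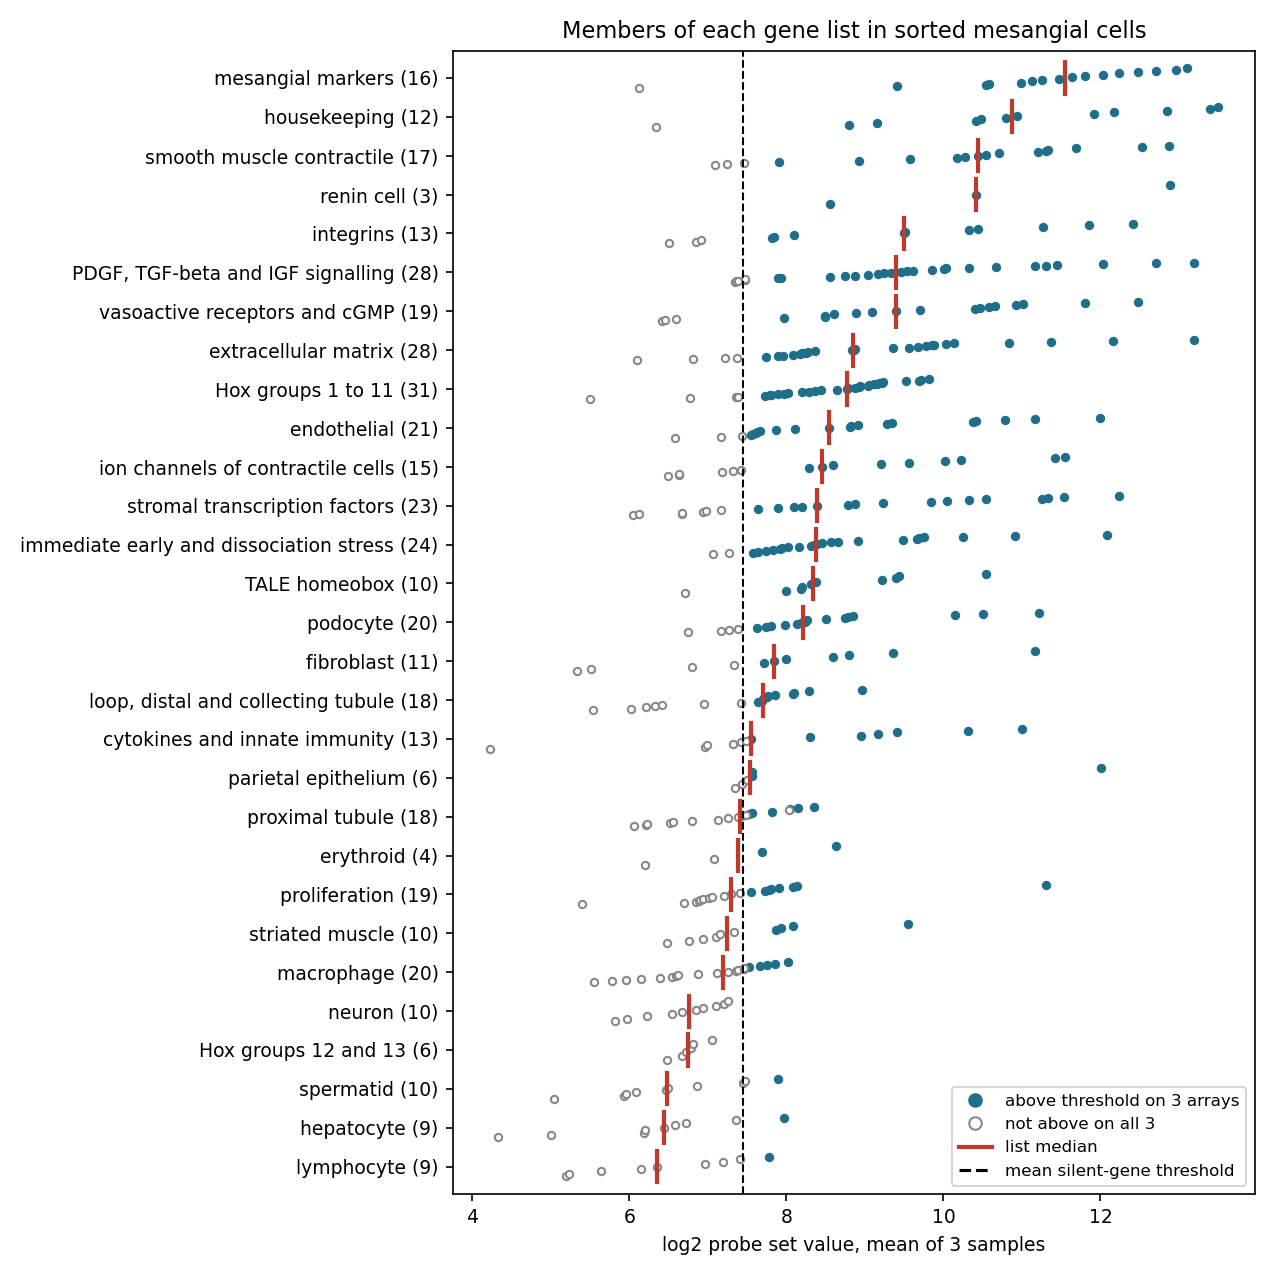
Mean log2 value over the 3 samples (horizontal axis) of every measured member of the 29 gene lists (vertical axis, number of measured members in brackets). Filled points lay above the silent-gene threshold on all 3 arrays, open points did not, red bars are list medians and the dashed line is the mean threshold of 7.45. The mesangial list has 15 of 16 points to the right of the line, and the lymphocyte list 1 of 9.

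Immediate early and stress genes, which tissue dissociation is known to induce, were mostly above the threshold. Of the 24 measured 22 passed (adjusted p = 0.00742, Fisher's exact test), with the chaperone gene Hsp90aa1 at 12.08 ± 0.44, the phosphatase gene Dusp1 at 10.91 ± 0.12 and the transcription factor gene Klf6 at 10.25 ± 0.05, and with Maff at 7.07 not above it. At the threshold raised by 1, 10 of 24 remained and the share did not pass (adjusted p = 0.486, Fisher's exact test). Of 13 cytokine and innate immunity genes 7 passed (adjusted p = 0.875, Fisher's exact test), with the adhesion molecule gene Vcam1 at 11.23, 10.74 and 11.04 in samples 1, 2 and 3, the endotoxin receptor gene Tlr4 at 10.31, the chemokine gene Cxcl10 at 9.41 ± 1.10 and Il6, at 4.22, not above it. Of 19 proliferation genes 8 passed (adjusted p = 0.260, Fisher's exact test), and only Pcna, a DNA replication clamp, at 11.30 ± 0.03 passed the threshold raised by 1 (adjusted p = 0.0348, Fisher's exact test). The replication helicase genes Mcm4 and Mcm6 had 8.14 and 8.09 ± 0.17, and the mitotic checkpoint gene Bub1, at 5.40, was not above it. Of 12 housekeeping genes 11 passed (adjusted p = 0.0408, Fisher's exact test), with Actb at 13.50 ± 0.08, B2m at 13.40 ± 0.05 and Eef1a1 at 12.84, and with Tfrc at 6.33 not above it. At the mean of the arrays the housekeeping share did not pass (adjusted p = 0.0719, Fisher's exact test), and at the threshold raised by 1 it did (adjusted p = 0.000344, Fisher's exact test).

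The 20 named genes with the highest means had values from 13.09 to 13.79 and are given without order. They held the mesangial, matrix and growth factor genes Ptn, Sparc and Igfbp7, the secreted Wnt modulator gene Sfrp2, the cytoskeletal genes Actb, Tmsb10 and Myl6, the calmodulin gene Calm2, the sodium-potassium-chloride cotransporter gene Slc12a2 and Baiap2l1. The others were B2m, Fth1, Ifitm3, Serinc3, Tpt1, Itm2b, Ddx5 and the non-coding RNAs Malat1, Gas5 and Rn7sk.

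The 3 samples were close to one another. Across the 18686 named genes, which are not independent replicates, Pearson's r was 0.995 for samples 1 and 2, 0.995 for samples 1 and 3 and 0.997 for samples 2 and 3, and Spearman's rho was 0.994, 0.994 and 0.997. Part of this closeness lies in identical values, which 59.7%, 57.8% and 63.4% of the genes had in these pairs. Over the 3974 genes without ties, chosen after the data were seen, r was 0.980 to 0.987. Among genes above the threshold, 29, 33 and 30 differed by more than 2-fold in these pairs. Their median SD was 0.02, or 0.07 without the genes that had 1 identical value, and 78 had an SD over 0.5. Cwc22, a splicing factor gene, varied most, with 9.68, 12.80 and 11.89 in samples 1, 2 and 3, an 8.70-fold range. The serotonin receptor gene Htr1b had 7.77, 7.89 and 10.07, the heat shock gene Hsph1 8.35, 8.18 and 9.82, and the clock gene Arntl 7.76, 7.81 and 9.22. Cxcl10 had 9.62, 10.39 and 8.21, the guanylate-binding protein gene Gbp8 10.29, 11.88 and 10.60, and the matrix gene Tnc 9.67, 7.89 and 9.03. Lsamp had 9.10, 7.47 and 7.46, Gm10825 7.66, 9.86 and 8.75, and Gm8995 7.61, 9.39 and 9.09. These genes were picked for their spread, and no test of a difference between single samples was possible.

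**Figure D3:**
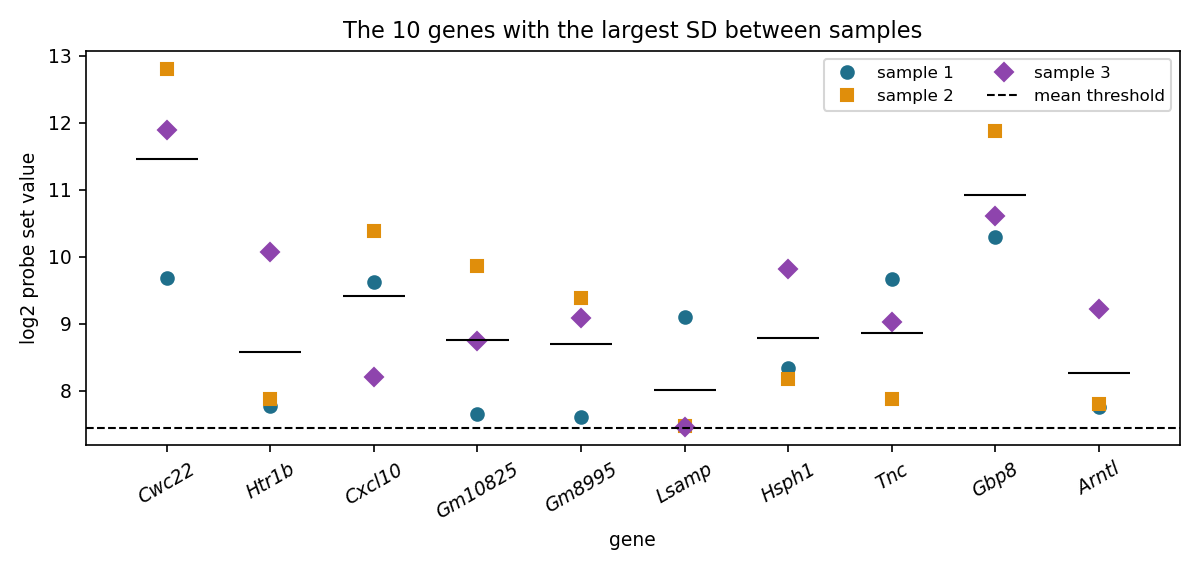
Log2 probe set value (vertical axis) in each of the 3 samples for the 10 genes above the threshold with the largest SD (horizontal axis). Horizontal bars are the mean of the 3 samples and the dashed line is the mean silent-gene threshold of 7.45. Sample 3 has the highest value for Htr1b, Hsph1 and Arntl, sample 2 for Cwc22, Cxcl10, Gm10825, Gm8995 and Gbp8, and sample 1 for Lsamp and Tnc.

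The median deviation of each gene list in each sample was at most 0.08 in size. Of 87 list shifts, 29 lists on 3 arrays, 10 lay outside the central 95% of random lists matched on level. For lists of random genes 4.35 would. Without sample 1, 8 of 58 lay outside, and without sample 2 or sample 3, 4 of 58, where 2.90 would for lists of random genes. Genes of a fixed list may vary together, so 4.35 and 2.90 are not the numbers to expect for such lists. Shifts of a list on different arrays are not independent. With 1 sample left out they mirror each other, so each list outside is counted on both arrays. In the full count every list outside lay outside on more than 1 array, so the counts overstate the number of separate lists. Contractile smooth muscle genes had the largest of the shifts, a median deviation of 0.08 in sample 3 (99.97th percentile) and -0.04 in sample 2 (0.670th percentile). The other shifts outside were at most 0.04 in size, for parietal epithelial, podocyte, mesangial and later tubule genes. Identical values hold such medians near 0. By the mean of the deviations, chosen after the data were seen, 16 shifts lay outside. Among them were smooth muscle (-0.10 in sample 2 and 0.10 in sample 3), proximal tubule (0.09 in sample 1 and -0.11 in sample 3) and extracellular matrix (-0.08 in sample 2 and 0.06 in sample 3). Immediate early and stress genes lay outside in the same direction as the matrix (-0.05 in sample 2 and 0.05 in sample 3), and so did cytokine genes in the opposite one (0.06 in sample 2 and -0.09 in sample 3). By the median, the proximal tubule, matrix, stress and cytokine lists had shifts of 0 in every sample. The cytokine means rested largely on Cxcl10, the stress means on Hspa1a and Hsp90aa1, and the proximal tubule means on Kap and Miox. The matrix mean of sample 2 rested largely on Tnc and Thbs1. All of these were seen after the fact. Kap and Miox were not above the threshold on all 3 arrays.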

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

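Chosen only after the data were seen were the threshold raised by 1, the mean of deviations and the correlations over genes without ties. Of 406 results on list shares, 343 kept their side of the test and their direction, 34 were no longer called, 12 became called and 17 changed direction, 2 of which (later tubule) also became called. No call of a list share moved with quantile normalization or the mean of several probe sets. Both changed the data little, with 10828 and 10734 genes above the threshold against 10833, so they are a weak check. Median-centring cannot move a call, because the threshold moves with the array. Among the limits are signal over background, since many members lie within 1 of the threshold, the identical values, the small lists and the number of arrays. Where a count or share below changed because the threshold moved, the alternative's construction is the cause, and otherwise the cause was not tested.

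At the 90th percentile 9 lists were called. No longer called there were the mesangial (93.8% above), macrophage (55%), lymphocyte (33.3%), vasoactive (84.2%) and housekeeping lists (91.7%), and parietal (83.3%), later tubule (61.1%), erythroid (75%), striated muscle (70%) and cytokine genes (76.9%) changed direction. At the 99th percentile 6596 genes were above, and with the threshold raised by 1, 6118. Under both, smooth muscle (76.5%), proximal tubule (0%) and proliferation (5.26%) became called. Endothelium (52.4% in both), extracellular matrix (53.6% and 50%), immediate early genes (45.8% and 41.7%), and lymphocyte, hepatocyte and Hox 12 and 13 genes (0%) lost their calls. Podocyte genes (30%) changed direction, later tubule genes (0%) changed direction and became called, and neuron and spermatid genes (0%) lost theirs at the threshold raised by 1 alone. With olfactory receptors alone, macrophage (35%), spermatid (30%), vasoactive (84.2%) and housekeeping genes (91.7%) lost their calls, and parietal (83.3%) and cytokine genes (61.5%) changed direction. With the mean of the arrays or 2 of 3 arrays, macrophage (35%), vasoactive (84.2%) and housekeeping genes (91.7%) lost their calls, and parietal (66.7%) and cytokine genes (61.5% and 69.2%) changed direction. Smooth muscle (88.2%) became called with 2 of 3 arrays. Without genes in several lists, mesangial (100%), vasoactive (81.3%) and growth factor genes (80.0%) lost their calls, and podocyte genes (84.2%) became called. With silent genes in the background, smooth muscle (82.4%), podocyte (80%) and TALE genes (90%) became called.

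Leaving out each sample gave 82.4% to 88.2% for smooth muscle, 50% to 66.7% for parietal, 25% to 35% for macrophage, 53.8% to 69.2% for cytokine and 84.2% throughout for vasoactive genes. The changes of call or direction came without sample 1, except the parietal one, which came without sample 2. The shifts outside numbered 4 to 8 of 58, with 4 without sample 2 or sample 3, and 16 of 87 by the mean of deviations. Among the 58, each list outside is counted on both arrays that were left. The lowest r between samples was 0.988 over genes above the threshold and 0.980 over genes without ties.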

Other observations

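The leukocyte test and both tests of identical values were chosen only after the result was seen, whereas the genes of the interferon and clock tests were listed without looking at their values, after other genes had shown each pattern. The random lists below describe these arrays only and give no spread between samples, so no difference between single samples was tested.

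Interferon-response genes were readily measured in these cells. Of 24 genes listed for the test, 23 lay above the threshold, among them Iigp1 at 12.50, 12.92 and 12.42 in samples 1, 2 and 3 and the immunoproteasome gene Psmb9 at 12.05, 12.43 and 11.95. Core clock genes were measured as well, with Nr1d1, a repressor of Arntl, at 11.45, 11.56 and 10.17. Not all clock genes were as clear. Nfil3, Ciart and Bhlhe41 were not above the threshold on every array, and Per2 (7.82, 7.82 and 7.81) lay within 1 of it. All of these genes were chosen after values were seen or for the tests below.

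Sample 2 had higher values of interferon-response genes than sample 3. Sample 1 was not part of this contrast. Among genes picked after their values were seen, sample 1 was lowest for Gbp8 and Irgm1 and between the other samples for Gbp5 and Cxcl9. The difference between samples 2 and 3 was seen in Cxcl10, Gbp8, Gbp9, Zbp1, Cd274 and Gm12250. In the 24 other genes its mean was 0.42, with 22 positive, 1 negative and 1 at 0, against a highest mean of 0.15 over random lists matched on level. A higher share of leukocytes in sample 2 cannot be told apart from it, because 6 of the 29 macrophage and lymphocyte markers lay above the threshold on all arrays and markers near background exclude little. Their mean difference was 0.0379 (bootstrap interval over genes from -0.01 to 0.10), and of genes chosen after their values were seen Ptprc was at 5.95 on each array, Lyz2 (6.41, 6.21 and 6.54) was lowest in sample 2, and Cd74 (7.11, 7.56 and 7.11) and H2-Aa (7.20, 7.78 and 7.18) passed the threshold in sample 2 alone. A difference in interferon exposure between the kidneys may be the source, as a hypothesis, and the design names no condition to test it against.

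Clock genes of opposite daily phase stood apart in sample 3, in which the heat shock genes Hsph1 (8.35, 8.18 and 9.82) and Hsp90aa1 (11.96, 11.72 and 12.56) were also highest. The mean deviation of the stress list, which holds Hsp90aa1, was highest there too (0.05), but its median deviation was 0. After Arntl (7.76, 7.81 and 9.22) and Nr1d1 had shown the clock pattern, 3 other genes of the Arntl phase (Clock, Cry1 and Nfil3) stood 0.79 above the mean of samples 1 and 2 and 9 of the Nr1d1 phase stood at -0.60, a difference of 1.39 against a highest of 0.72 over random lists. Without Nfil3, which carried most of the first part, it was 0.89 against a highest of 0.86, and its size is approximate because Nfil3, Ciart and Bhlhe41, 3 of the 12, were not above the threshold on every array. An offset of array 3 that depends on level is argued against, since the upper 2.5% of matched random lists began at 0.22. A different time of day at collection is a candidate explanation, as a hypothesis, the labels used here give no such time, and a difference in handling was not tested.

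Of all probe sets 40.2% held 1 identical value on the 3 arrays, and the share was 54.8% in part 4 of 10 equal parts by level and 13.2% in the highest. The same hybridisation deposited more than once is argued against, since the most alike pair of arrays shared 50.2% of its probe set values. Median polish, a robust summary of probes, of the 3 arrays is a candidate explanation. Simulated probe sets of 25 probes with no difference between arrays came out identical in 78.2% of 2000 cases with 3 arrays. That share is above the observed 40.2%, so the simulation shows only that such ties can arise. With 4 arrays 0 came out identical, which separates little. A median over an even number of arrays averages the middle values, so exact ties are hardly possible there. Other odd numbers of arrays were not simulated. The summary method used by the authors is not given in the sources used here. If it was median polish, an SD of 0 would be a property of the summary.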
